A study of Oryza sativa with 9 samples.

How the data were processed

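RNA from rice roots was measured on 9 one-colour Affymetrix rice arrays, with biotin-labelled cRNA from 1 sample on each array (20 ug of cRNA, per the labels). Samples were grouped by the labels as control, 48 h after inoculation and 96 h after inoculation, with 3 arrays each. The deposited values are on a log2 scale and were made by the authors with GCRMA, per the submitters' processing notes. GCRMA corrects background by probe GC content, normalizes by quantiles and summarises the probes of a probe set. Its version is not given in the sources used here, and the log base was inferred from the range of the values, 1.24 to 15.4. The array medians of the tested probe sets lay between 7.86 and 7.92. No arrays held the same values. Quantile normalization removes any overall difference in the amount of mRNA between samples, so changes are relative to the other probe sets of an array. Compared with the value in the sample, GCRMA values of dim probe sets are compressed towards a common floor, which makes their fold differences smaller.

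The deposited table holds 57258 rice probe sets and 123 array controls. The gene table gives 1 gene for 22436 probe sets, several for 95 and none for 34850 (array controls included), and no gene was named from the last 2 kinds. The 17905 genes were all found in the RefSeq gene table of assembly ASM3414082v1, and 2448 have a published name there. No coordinates are printed, since the arrays name no genome build. Probe sets over log2 5 on at least 3 of the 9 arrays were tested, 19801 in all, of which 14846 had 1 gene, for 13133 genes. Of the tested probe sets, 3987 carry a suffix marking probes shared between transcripts, so signals of near-identical family members, such as expansins or chitinases, can mix.

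Each comparison was made with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on all 9 arrays, which share 1 estimate of the spread with 6 residual degrees of freedom. Probe sets were called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were 48 h with control, 96 h with control, 96 h with 48 h, and the mean of both times with control. Adjusted p-values in the text are from limma, or from camera for lists. In simulated data with 200 changed probe sets, 33 of 100 changes of log2 1 and 85 of 100 changes of log2 2 were recovered for 48 h against control, with 9 false calls among 127. For 96 h against control, 37 and 83 of 100 were recovered, with 4 false calls among 124. The simulated noise was independent for each probe set and array, with no deviations shared across an array, so these rates may be too favourable for the real data. An exploratory fit of the real values came before this test, and the model was not changed after it. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

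Gene lists were fixed before the data were examined as description patterns and locus names. The gene tables hold neither, so the 35 lists were carried over to published gene names. This was done after the array controls, the quantiles of each array and the correlations between arrays had been seen, but before the values of any list member. Names were added or left out by reading the names alone. The cell cycle list became wider, taking in genes of the origin recognition complex and replication factors, as did the gibberellin list. The list of pathogenesis-related proteins holds PBZ1 and genes with chitinase names, among them CHIB3H-A, which also has the names RIXI and XIP-I of a xylanase inhibitor. The pectin list holds only endoglucanases. The jasmonate list takes in TIFY1A, TIFY2A and TIFY2B, which also have the names GATA18, GATA17 and GATA20 of GATA factors, and LOX3, also named r9-LOX1. Jasmonate genes here means the members of this list, whether or not each acts in jasmonate signalling. A gene was represented by its probe set of highest mean. Lists with at least 3 measured genes, 30 in all, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 30 lists of a comparison. fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. No list call at any comparison held with an estimated correlation. That correlation was 0.0155 for expansins, near the preset one, yet at 48 h their adjusted p went from 0.00645 to 0.491. So this setting can lose a call without much correlation between the genes. A lost call by itself does not show that correlation undid it, for any list. The estimated correlation was higher for every other called list, up to 0.977 for secondary wall genes.

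For each comparison with control the 10 largest rises and 10 largest falls were named among genes with a published name that passed limma and whose groups did not overlap. Where fewer than 5 passed, the 5 of lowest p in each direction were named. From each list up to 3 genes of lowest p were named. Genes without a published name were left out. Alternatives covered the filter on dim probe sets, renormalization, the variance model, array weights, the arrays in the fit, replicate number, harvest day and RNA yield as model terms, the thresholds, and leaving out each array in turn. Controls shared no harvest day with infected roots, so they could not be compared within a day. The arrays of each group came from different days, so variation between days is part of the spread the tests use. A difference common to the control days against the days of infected roots cannot be told apart from infection. Harvest day was fitted as a random block for those comparisons, and within-day values are given for 96 h against 48 h.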

Results

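Gene expression was measured in roots of rice (Oryza sativa) during the first days of infection by Meloidogyne graminicola, a root-knot nematode. The species is that of the infection label, and the treatment text of the labels also names Meloidogyne incognita. The data comprised 9 one-colour Affymetrix rice arrays: 3 from uninfected control roots, 3 from roots at 48 h (2 days) after inoculation and 3 from roots at 96 h (4 days). The labels give the controls no time, so each infected group was compared with the same 3 control arrays. The plants grew hydroponically, and each array held labelled cRNA from 1 RNA sample. Between 18711 and 19137 probe sets lay over log2 5 on each array, and 19801 probe sets were tested. The precision is limited by the 3 arrays per group. The 3 arrays of each group came from different harvest days, so they are separate harvests, and the spread between them includes differences between days. The labels do not say whether replicates came from separate cultures. The p-values measure the spread between these samples, which may be technical in part.

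The first principal component held 62.3% of the variance and separated the control arrays from the 96 h arrays. The array labelled 48 h replicate 3 lay at 72.0 on this component, beside 96 h replicates 1 and 2 at 71.4 and 78.9, while 48 h replicates 1 and 2 lay at -25.2 and -41.1. The array of 96 h replicate 3 lay at 34.4. All groups were kept as labelled, and counts without these arrays are given where they differ.

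**Figure D1:**
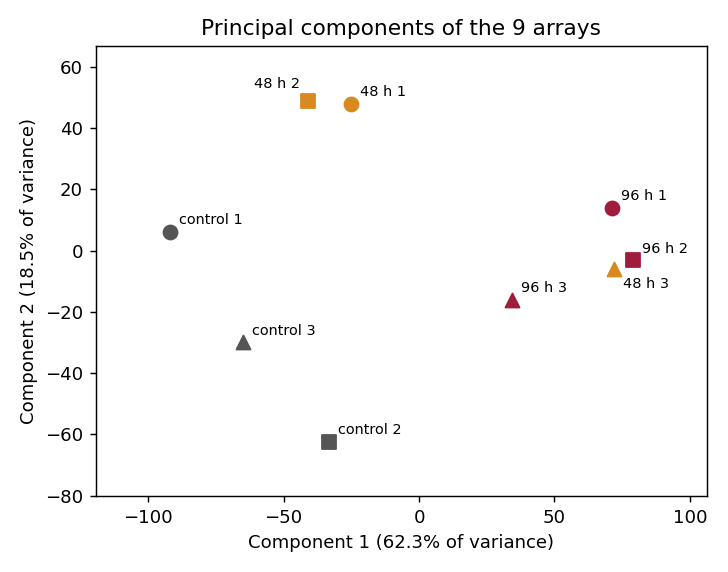
Each point is 1 of the 9 arrays, placed by its scores on the first (horizontal axis, 62.3% of variance) and second (vertical axis, 18.5%) principal components of the tested probe sets, which have no unit. Colours mark the groups and shapes the replicate numbers; 48 h replicate 3 sits at 72.0 on the first component, next to 96 h replicates 1 and 2.

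The comparison of 48 h with control asked which root transcripts had changed within 2 days of inoculation. In infected roots 4 of 11 genes for pathogenesis-related proteins, 6 of 22 expansin genes and 5 of 28 jasmonate genes rose. These lists passed camera with the preset correlation and not with an estimated one (adjusted p = 0.491, 0.491 and 0.577 with an estimated correlation). With fry the pathogenesis-related and expansin lists passed (adjusted p = 0.0144 and 0.00316) and the jasmonate list did not (0.05002). PBZ1 (LOC4352491), a probenazole-inducible protein of the PR10 family, rose from 4.41 ± 1.25 to 8.93 ± 1.41 (log2 mean ± SD, n = 3). EXPA7 (LOC4334606), an expansin that loosens cell walls, rose from 7.74 ± 0.35 to 11.37 ± 0.56, and AMT2-2 (LOC4327434), an ammonium transporter gene, fell from 7.07 ± 0.38 to 5.46 ± 0.12 (n = 3 each). In all, limma called 559 probe sets at an adjusted p under 0.05, 385 higher and 174 lower, and 3588 had an unadjusted p under 0.05. Groups did not overlap for 22.8% of the tested probe sets, against 10% by chance.

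PDC1 (LOC4339066), a pyruvate decarboxylase of ethanol fermentation, rose from 3.07 ± 0.14 to 9.73 ± 2.15 (log2 mean ± SD, n = 3), a difference of 6.66 ± 1.35 (SE; limma adjusted p = 0.0438). MEAL1 rose by 4.79 ± 0.44 (limma adjusted p = 0.00298) and WOX10, a WUSCHEL-related homeobox gene, by 4.04 ± 0.38 (limma adjusted p = 0.00298). MADS25, a MADS-box transcription factor gene, rose 12.5-fold, from 6.35 ± 0.25 to 9.99 ± 0.18 (SD, n = 3). BGLU26, a beta-glucosidase gene, rose from 3.19 ± 0.70 to 6.84 ± 0.19, and TPP3, a trehalose-6-phosphate phosphatase gene, from 2.33 ± 0.33 to 5.93 ± 1.45. Among the genes that fell, HOX12, a homeodomain-leucine zipper gene, changed by -2.53 and PDIL1-2, a protein disulfide isomerase-like gene, by -1.94 (log2). GATA15 changed by -1.82, the blue-light receptor gene PHOT1A by -1.79 and UGE-1, a UDP-glucose 4-epimerase gene, by -1.68. KCO2, a potassium channel gene, changed by -1.54 and the zinc finger gene OsC3H39 by -1.30. SAT4, a serine acetyltransferase gene, and NCL1 changed by -1.09 and -1.06. The control means of PDC1, MEAL1, PBZ1, WOX10, BGLU26, TPP3, CHT11 and CYP99A3, and the 48 h means of HOX12, GATA15, KCO2 and OsC3H39, lay under log2 5, among the dim probe sets, so the sizes of these differences are uncertain.

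Of 11 measured genes for pathogenesis-related proteins, mostly chitinases, 4 rose at 48 h over all probe sets, and 10 rose and 1 fell when adjusted over the list alone. The chitinase genes CHT11 and CHIA1A rose by 3.28 ± 0.27 and 3.79 ± 0.65 (log2 ± SE). The list ranked higher than other genes (camera adjusted p = 1.07e-06 with the preset correlation), with adjusted p = 0.491 with an estimated correlation. Of 22 expansins, 6 rose and 0 fell over all probe sets, and 9 rose and 1 fell adjusted over the list alone. EXLA3 rose by 2.20 and EXPA2 by 1.89. The expansin list had a camera adjusted p of 0.00645, and adjusted p = 0.491 with an estimated correlation. Of 28 jasmonate genes, 5 rose, and 7 rose adjusted over the list alone. They included the repressor genes TIFY10C (3.08 ± 0.34) and TIFY10B (1.06 ± 0.19) and the lipoxygenase gene LOX5 (0.91 ± 0.18). The camera adjusted p of the jasmonate list was 0.000548, and adjusted p = 0.577 with an estimated correlation.

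Genes of the cell cycle and DNA replication ranked higher at 48 h as a list (camera adjusted p = 2.4e-06; adjusted p = 0.725 with an estimated correlation). The median difference of its 49 members was 0.34, and 42 were positive, but 1 member, the D-type cyclin gene CYCD3;2, rose by itself (1.81 ± 0.24; limma adjusted p = 0.0107), also adjusted over the list alone. Of 6 histone genes, H2B.10 rose by 0.95, and 2 rose adjusted over the list alone. The histone list had a camera adjusted p of 0.00386 (adjusted p = 0.725 with an estimated correlation). Of 15 diterpenoid phytoalexin genes on the array, 3 passed the filter on dim probe sets. Their control means were 3.48, 2.24 and 2.63, so they passed it only through infected arrays. The filter thus favours a rise of this list in every comparison with control, and the genes left out are not covered. The list of 3 genes ranked higher (camera adjusted p = 0.0350, and adjusted p = 0.725 with an estimated correlation). None of its members passed limma over all probe sets, and 2 rose adjusted over the list alone. CYP99A3 had a difference of 2.92 ± 0.75. The camera adjusted p of this list was 0.0576 and 0.0763 without control replicates 1 and 3 and 0.0931 without 48 h replicate 3 (range over its alternatives 0.0143 to 0.725). All 4 secondary wall genes, among them the cellulose synthase genes CESA4 (-1.48 ± 0.47), CESA7 (-1.29 ± 0.44) and CESA9 (-1.56 ± 0.49), had lower means. This list ranked lower (camera adjusted p = 0.00645, and adjusted p = 0.725 with an estimated correlation). Over all probe sets 0 members passed limma, and 3 were lower adjusted over the list alone. With fry the cell cycle, histone, diterpenoid and secondary wall lists did not pass (adjusted p = 0.162, 0.122, 0.167 and 0.167). Of 24 genes of the cellulose synthase family, 2 rose, CSLC9 (1.51 ± 0.14) and CSLA9 (0.97 ± 0.16), and 3 rose adjusted over the list alone, while the list did not pass (camera adjusted p = 0.764).

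Single arrays decided much of the 48 h count. It was 122 without 48 h replicate 1, 277 without 48 h replicate 2, 172 without control replicate 2, 162 without control replicate 3, and 275 and 257 without 96 h replicates 1 and 2. Without 48 h replicate 3, which lay beside the 96 h arrays, it was 469. Of the 559 calls, 342 were among these. Of the 20 genes named by rank, the calls of 7 (MEAL1, WOX10, MADS25, EXPA7, CHT11, GATA15 and AMT2-2) held without any 1 of the 9 arrays. The calls of PDC1, PBZ1, TPP3, PHOT1A, KCO2 and NCL1 held in 2 of the 9 fits that left out 1 array.

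**Figure D2:**
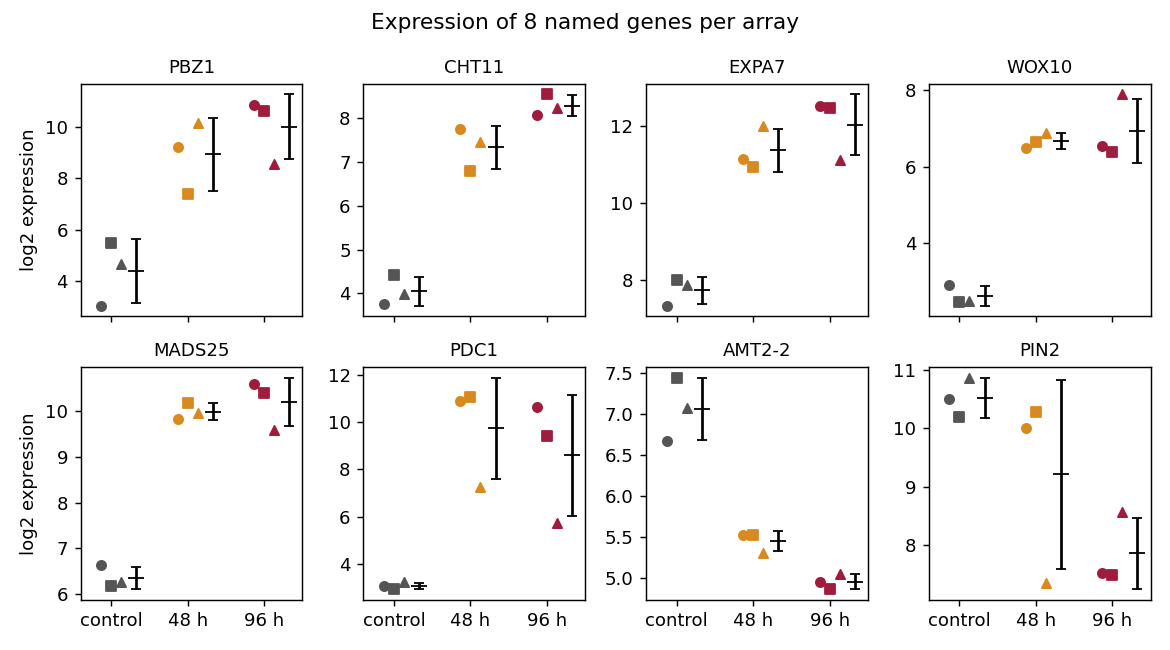
Log2 expression (vertical axes) of 8 named genes on each array, by group (horizontal axes), with the group mean and SD as a bar beside the points; shapes mark replicate numbers. EXPA7 rose from a control mean of 7.74 to 11.37 at 48 h and 12.04 at 96 h, while AMT2-2 fell from 7.07 to 5.46 and 4.96.

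The comparison of 96 h with control asked which transcripts differed after 4 days. Of the genes for pathogenesis-related proteins 8 of 11 rose, as did 13 of 28 jasmonate genes and 4 of 12 endoglucanase genes, while 9 of 22 expansin genes rose and 1 fell. These lists passed camera with the preset correlation and not with an estimated one (adjusted p = 0.489, 0.489, 0.557 and 0.489 with an estimated correlation). They also passed fry (adjusted p = 0.00344, 0.00344, 0.0101 and 0.00119). PBZ1 reached 10.01 ± 1.26 against 4.41 ± 1.25 in controls (log2 mean ± SD, n = 3). GER6 (LOC4344843), a germin-like protein gene, rose from 6.76 ± 1.21 to 11.72 ± 0.23, and PIN2 (LOC4341736), an auxin efflux carrier gene, fell from 10.52 ± 0.34 to 7.86 ± 0.61 (n = 3 each). limma called 2346 probe sets, 1438 higher and 908 lower, and 6287 had an unadjusted p under 0.05. The split was 1240 higher and 1063 lower after quantile normalization, and 2377 higher and 2401 lower without both replicate 3 arrays of the infected roots, an alternative chosen after seeing the data. Groups did not overlap for 39.4% of probe sets, against 10% by chance.

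Among the other large rises at 96 h, the chitinase genes CHIA2A and CHIA1A rose by 4.77 ± 0.82 and 4.48 ± 0.65 (log2 ± SE; limma adjusted p = 0.0144 and 0.00871), and CHIB3H-A, also named RIXI and XIP-I after a xylanase inhibitor, by 4.41 ± 1.13 (limma adjusted p = 0.0429). GLU14, an endoglucanase gene, rose 26.9-fold, PDC1 rose to 8.59 ± 2.55 and MEAL1 to 9.28 ± 1.01 (log2 mean ± SD, n = 3), from control means of 3.07 and 4.72. WOX10 and EXPA7 rose by 4.31 ± 0.38 and 4.30 ± 0.43. Another expansin gene, EXPA29, fell from 7.12 ± 0.80 to 4.07 ± 0.85 (limma adjusted p = 0.0222). HXK4, a hexokinase gene, changed by -2.58, the formin gene FH2 by -2.43 and VIT1, a vacuolar iron transporter gene, by -2.43. PDIL1-3 and PDIL1-2 changed by -2.49 and -2.21, HOX12 by -2.17, the growth-regulating factor gene GRF1 by -2.17 and CPK6, a calcium-dependent protein kinase gene, by -2.12. At 96 h too, the size of a difference is uncertain where a mean lay under log2 5, as in controls for PBZ1, PDC1, MEAL1, CHIB3H-A, WOX10, CHT11, LOX9, CEL9E, CYP99A3 and CYP71Z7, and at 96 h for EXPA29, FH2, HOX12, CPK6, AMT2-2 and CYP71Z7.

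Of 28 jasmonate genes, 13 rose and 0 fell at 96 h, and 14 rose adjusted over the list alone. TIFY10C rose by 3.62, TIFY10B by 1.59 and the lipoxygenase gene LOX9 by 3.83. The list had a camera adjusted p of 8.55e-06, and adjusted p = 0.489 with an estimated correlation. Of 11 genes for pathogenesis-related proteins, 8 rose, and 9 adjusted over the list alone, with CHT11 at 4.22 ± 0.27. The camera adjusted p was 1.33e-05, and adjusted p = 0.489 with an estimated correlation. CYP99A3 (3.81 ± 0.75) and CYP71Z7 (2.61 ± 0.58), cytochrome P450 genes of the diterpenoid list, rose, and all 3 members rose adjusted over the list alone. These 3 members passed the filter on dim probe sets only through infected arrays, which favours a rise. That list had a camera adjusted p of 0.0399 (fry adjusted p = 0.0352), and adjusted p = 0.727 with an estimated correlation. Without control replicate 2 its camera adjusted p was 0.0729 (range over its alternatives 0.0144 to 0.727).

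Cell wall genes went both ways at 96 h. Of 22 expansins, 9 rose and 1 fell, and 12 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.0432; adjusted p = 0.489 with an estimated correlation). Leaving out control replicate 2, 48 h replicate 2 or 48 h replicate 3 gave the expansin list a camera adjusted p of 0.0776, 0.0531 or 0.0679 (range over its alternatives 0.00119 to 0.489). Of 12 members of the pectin and endoglucanase list, all of which are endoglucanase genes, 4 rose, and 6 rose and 1 fell adjusted over the list alone. GLU11 rose by 3.28 and CEL9E by 2.90, with a camera adjusted p of 0.0491 for the list and adjusted p = 0.557 with an estimated correlation. Its camera adjusted p was 0.0546, 0.0776 and 0.0566 without control replicates 1, 2 and 3, 0.0530 and 0.0519 without 48 h replicates 1 and 2, and 0.0551 and 0.145 without 96 h replicates 1 and 3 (range over its alternatives 0.0101 to 0.557). The 4 secondary wall genes had a mean difference of -1.41 (camera adjusted p = 0.0489; adjusted p = 0.857 with an estimated correlation). None passed limma over all probe sets, and all 4 fell adjusted over the list alone. The camera adjusted p of the secondary wall list was 0.0992 and 0.0566 without control replicates 2 and 3, 0.0576 and 0.0679 without 48 h replicates 2 and 3, and 0.0930 and 0.0743 without 96 h replicates 1 and 2 (range over its alternatives 0.000705 to 0.857). On the arrays this list stood at -2.10 and -1.96 in 96 h replicates 1 and 2, and at -0.18 in 96 h replicate 3, the same value as control replicate 1.

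Ribosomal protein genes ranked slightly lower at 96 h, with a median difference of -0.21 over 25 genes of which 1 was positive (camera adjusted p = 0.0196; adjusted p = 0.857 with an estimated correlation). None of the 25 passed limma, over all probe sets or adjusted over the list alone. Leaving out control replicate 3 or 96 h replicate 3 gave the ribosomal list a camera adjusted p of 0.0566 or 0.0628 (range over its alternatives 0.000628 to 0.857). Of 11 amino acid, peptide and nitrogen transporters, AMT2-2 (-2.10) and AMT2-1 (-0.97) fell and PROT1 (0.90) rose, and 5 fell and 1 rose adjusted over the list alone. The camera adjusted p was 0.0489, and adjusted p = 0.824 with an estimated correlation. It was 0.0776 and 0.0653 without control replicates 2 and 3, 0.0576 and 0.0679 without 48 h replicates 2 and 3, and 0.0699 and 0.0682 without 96 h replicates 1 and 2 (range over its alternatives 0.0103 to 0.824). CYCD3;2 rose by 2.21, while CYCD4;1 and CDKA;1 fell by 0.83 and 0.72 on the log2 scale, and the cell cycle list did not pass (camera adjusted p = 0.171). With fry the ribosomal, nitrogen transporter and secondary wall lists did not pass at 96 h (adjusted p = 0.130, 0.0651 and 0.134).

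With harvest day as a random block, the expansin and nitrogen transporter lists had camera adjusted p-values of 0.0516 and the endoglucanase and secondary wall lists of 0.0533 at 96 h. The 3 prime minus 5 prime difference of actin, a measure used for RNA quality, was 6.37 ± 0.311 at 96 h and 5.63 ± 0.623 at 48 h against 5.56 ± 0.303 in controls (SD, n = 3), while that of cyclophilin was 1.45 ± 0.109 against 1.44 ± 0.180. With the mean of 2 actin probe set pairs as a covariate, an alternative chosen after seeing the data, the 96 h count was 46, and with the log2 RNA yield it was 466. The count was 1033 and 510 without control replicates 1 and 3, 1437 without 48 h replicate 1, 349 and 430 without 96 h replicates 1 and 2, 4472 without 48 h replicate 3, and 4778 without both replicate 3 arrays of the infected roots. Calls of 5 of the 20 genes named by rank (MEAL1, CHIA1A, WOX10, EXPA7 and PDIL1-2) held without any 1 array, while those of CHIB3H-A, PIN2, HXK4, FH2 and CPK6 held in 2 of the 9 fits that left out 1 array, and those of PDC1, GLU14 and PDIL1-3 in 3.

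**Figure D3:**
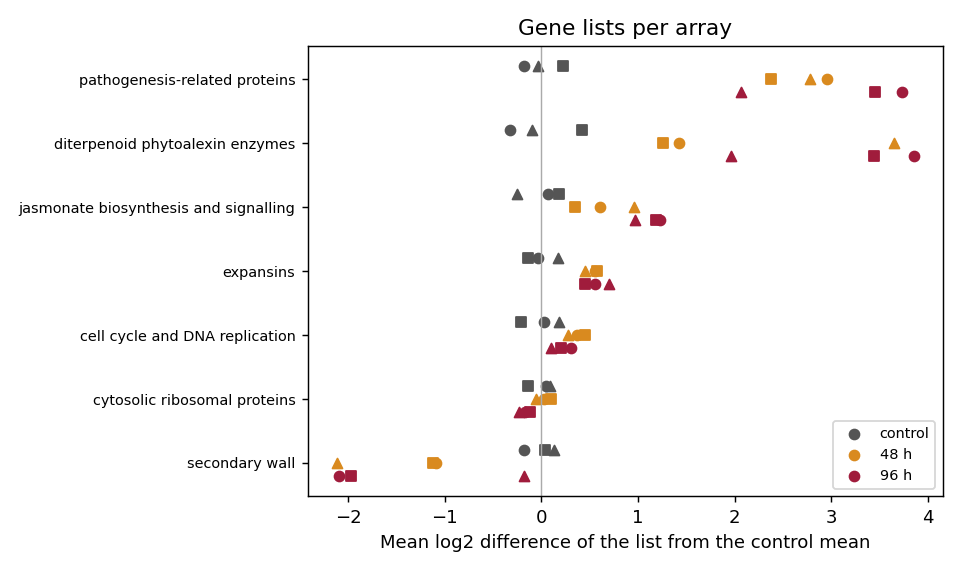
Mean log2 difference of 7 gene lists from the control mean (horizontal axis) on each of the 9 arrays, by list (vertical axis); colours mark the groups and shapes the replicate numbers. The secondary wall list stands at -2.10 in 96 h replicate 1 but at -0.18 in 96 h replicate 3.

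The direct comparison of 96 h with 48 h asked whether expression differed between the times. No probe set passed: limma called 0, and 1741 had an unadjusted p under 0.05, while groups did not overlap for 14.0% of probe sets, against 10% by chance. The named genes of lowest p did not pass (limma adjusted p = 0.464). They included the laccase gene LAC3, with a difference of 1.83 ± 0.45 (log2 ± SE), and PAL06, a phenylalanine ammonia-lyase gene, with 1.17 ± 0.30. The protein kinase gene WNK5 had 0.84 ± 0.21, CLE202 had 0.80 ± 0.22 and the cytokinin-activating gene LOG had 0.79 ± 0.22, an uncertain size since its 48 h mean, 4.39, lay under log2 5. On the lower side were Rac1 (-0.69 ± 0.20), KIN14I (-0.68 ± 0.22), GF14G (-0.58 ± 0.18), RYMV1 (-0.58 ± 0.19) and OsC3H14 (-0.53 ± 0.18).

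As lists, jasmonate genes (mean difference 0.49; camera adjusted p = 0.00107) and germin-like genes (1.52; camera adjusted p = 0.00838) ranked higher at 96 h than at 48 h. Ribosomal protein genes (-0.20; camera adjusted p = 8.26e-05) and cell cycle genes (-0.17; camera adjusted p = 0.00345) ranked lower. For each of the 4, adjusted p = 0.601 with an estimated correlation, and no member passed limma over all probe sets or adjusted over the list alone. Members of lowest p were TIFY1A, also named GATA18 (0.51), TIFY11C (1.69), GER6 (2.60), 60SP0 (-0.35), RPS4 (-0.29), CYCA2;1 (-0.55) and CYCB2;2 (-0.53). On the 2 harvest days that held both times, the 96 h minus 48 h difference was 0.58 and 0.27 for jasmonate genes and -0.15 and -0.12 for ribosomal protein genes. It was 1.73 and -0.10 for germin-like genes and -0.17 and 0.03 for cell cycle genes, so these differences did not hold on both days. Each day held 1 array per time, and the day of the second value is that of 48 h replicate 3, the array that lay beside the 96 h arrays.

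The count of 0 rested on 48 h replicate 3: without it limma called 2122 probe sets, and without both replicate 3 arrays of the infected roots 2552, the latter chosen after seeing the data. With harvest day as a fixed block over the 4 arrays of those 2 days, also chosen after seeing the data, the count was 0, with 272 at an unadjusted p under 0.05. That fit leaves 1 residual degree of freedom, so its count says little. At least 2-fold, 1894 probe sets were higher and 1354 lower at 96 h on the day of 48 h replicate 1 and 96 h replicate 2, and 248 and 135 on that of 48 h replicate 3 and 96 h replicate 1. The differences of the 2 days had r = -0.191 across probe sets, which are not independent replicates. Without 96 h replicate 3 the cell cycle list had a camera adjusted p of 0.111 (range over its alternatives 0.000194 to 0.601) and the germin-like list one of 0.0707 (0.00273 to 0.601).

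In the comparison of the mean of both times with control, 1908 probe sets passed limma, 1166 higher and 742 lower, with 5546 at an unadjusted p under 0.05. Groups did not overlap for 15.9% of probe sets, against 2.38% by chance. Of 11 genes for pathogenesis-related proteins 9 rose, and 10 rose and 1 fell adjusted over the list alone (camera adjusted p = 5.06e-06; adjusted p = 0.395 with an estimated correlation). Of 28 jasmonate genes 9 rose, and 13 adjusted over the list alone (camera adjusted p = 1.80e-05; adjusted p = 0.395 with an estimated correlation). Of 22 expansins 8 rose and 1 fell, and 11 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0220; adjusted p = 0.395 with an estimated correlation). The cell cycle (camera adjusted p = 0.00244), histone (0.0395) and diterpenoid (0.0230) lists ranked higher, and the secondary wall (0.0220) and nitrogen transporter (0.0415) lists lower. For these 5, the adjusted p with an estimated correlation lay between 0.709 and 0.844. Of them the diterpenoid list passed fry (adjusted p = 0.0473), and the others did not (0.0841 to 0.154). Over all probe sets 2 cell cycle genes rose and 2 fell, 1 histone gene and 2 diterpenoid genes rose, 0 secondary wall genes passed limma and 2 nitrogen transporters fell. Adjusted over the list alone, 2 rose and 2 fell, 2 rose, 3 rose, 4 fell, and 1 rose and 3 fell, in the same order. Without control replicate 2 the cell cycle and secondary wall lists had camera adjusted p-values of 0.0827 (range over its alternatives 2.15e-05 to 0.844) and 0.0633 (0.000355 to 0.736). The histone list had 0.113 and 0.0888 without control replicates 1 and 2, 0.0534 and 0.0918 without 48 h replicates 1 and 2, and 0.0628 without 96 h replicate 1 (0.00528 to 0.844). The nitrogen transporter list had 0.0827 and 0.111 without control replicates 2 and 3, 0.0669 and 0.0741 without 48 h replicates 2 and 3, and 0.0628 and 0.0525 without 96 h replicates 1 and 2 (0.00724 to 0.736). The count was 982, 921 and 521 without control replicates 1, 2 and 3, 1187 without 48 h replicate 1, and 892 and 882 without 96 h replicates 1 and 2. It was 672 with the actin covariate and 773 with the log2 RNA yield.

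The responses at 48 h and 96 h were correlated across the 19801 probe sets, which are not independent replicates (Pearson r = 0.842, covariance 0.491). Both responses share the control arrays: unchanged groups simulated against them gave a mean r of 0.474 and a covariance of 0.0628, so the covariance differed by 0.429. The 2 sets of calls shared 364 higher probe sets (28 expected for independent lists of 385 and 1438) and 155 lower ones (8 expected), and 0 were opposite. With 3 controls no split into separate control sets was made, and part of the excess may come from the shared controls. Without 48 h replicate 3, r was 0.537 and the covariance 0.300. Unchanged groups of those sizes, simulated after these values were seen, gave a mean r of 0.628 (0.607 to 0.648) and a covariance of 0.0628 (highest 0.0675). So r did not exceed the simulated value there, while the covariance did, by 0.237 on average. The simulated noise was drawn independently for each probe set, without deviations that many probe sets share on an array. The simulated ranges are therefore too narrow to judge the observed values by. Without control replicate 3 the simulated covariance had a mean of 0.146.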

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

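The tests on array position, actin and mature root tissue were chosen only after the results had been seen, while the counts over other splits of the samples were planned. For 96 h against 48 h limma called 0 probe sets (1741 at an unadjusted p under 0.05), while 4 lists passed camera with the preset correlation, the test of a difference between the times. They were ribosomal protein genes (camera adjusted p = 8.26e-05), jasmonate genes (0.00107), cell cycle genes (0.00345) and germin-like genes (0.00838), each with adjusted p = 0.601 with an estimated correlation. On the 2 harvest days that held both times the difference was 1.73 and -0.10 for germin-like genes and -0.17 and 0.03 for cell cycle genes. Each day held 1 array per time, and the second values are from the day of 48 h replicate 3, which lay beside the 96 h arrays. A small difference was likely on that day, so the change of sign says little. WNK5 lay below the control mean on every 48 h array and above it on every 96 h array, with a difference of 0.84 between the times; this was not tested as an interaction, and its limma adjusted p for 96 h against 48 h was 0.464.

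The array labelled 48 h replicate 3 lay with the 96 h arrays. On a scale from the other 48 h arrays (0) to the other 96 h arrays (1), its median over 3068 probe sets was 0.98 (quartiles 0.84 and 1.10), which a single wrong time label or a response as far on as at 96 h would both give, and these cannot be separated here. It had r = 0.985 with 96 h replicate 1 of its own harvest day and 0.992 with 96 h replicate 2 of another day. On both days that held both times the 48 h array was less like the 96 h array of its own day than that of the other (differences in r of -0.0162 and -0.0077, mean -0.0119). But 48 h replicate 2, of neither day, also had a lower r with 96 h replicate 2 (0.894) than with 96 h replicate 1 (0.907). The first difference may thus reflect the positions of the 96 h arrays. With 1 pair of arrays per day, harvest day as a cause is not decided. An exchange with 96 h replicate 3 stays open, since that array lay at 0.70 with quartiles of 0.40 and 0.99. A biological difference in the pace of infection was not tested. The actin 3 prime minus 5 prime difference of 48 h replicate 3, the mean of 2 probe set pairs, was 5.12. It was 4.69 and 4.14 on 48 h replicates 1 and 2, 5.20 to 5.63 at 96 h and 4.27 to 4.75 in controls. Whether a difference in sample quality contributes to the position of this array was not tested.

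The 3 prime minus 5 prime difference of actin was larger at 96 h than in controls by 0.778, the mean of 2 probe set pairs. Cyclophilin, GAPDH and ubiquitin moved by a mean of 0.083 (largest group SD 0.117). This argues against degraded RNA as the whole cause only if these genes register it as actin does. That was not tested: their control means were 1.44, 2.86 and 0.082, against 5.56 and 3.60 for the 2 actin pairs. On 96 h replicate 3 GAPDH stood at 3.29, above the controls (2.70 to 2.93), but at 2.80 and 2.77 on 96 h replicates 1 and 2. The 3 prime actin probe sets were lower at 96 h (-0.406, largest group SD 0.227) and the 5 prime ones lower still (-1.18). A lower transcript level by itself would lower both ends alike, but their shifts differed by 0.778 (largest group SD 0.264). So a lower level alone would not give the wider difference if both ends register it alike, which was not tested. The origin of the wider difference stays open. The covariate that took the 96 h count to 46 follows the groups, so it also removes part of the difference between them.

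Secondary wall genes had lower means in infected roots, by -1.41 at 96 h. A smaller share of mature root tissue may contribute, but mature-root transporters and CASP1, a Casparian strip gene, differed by 0.26 with a largest group SD of 1.16, so this cannot be told apart from chance with 3 controls that spread from -1.23 to 1.07. Of the lists standing for other tissues, the root hair gene CSLD1 had a difference of -3.05 ± 1.03 and the photosynthesis genes PSAG and OEE3 of 0.63 ± 0.64 and 0.55 ± 0.63 at 96 h (log2 ± SE), none past limma; the control mean of OEE3 lay under log2 5. A biological change of wall formation was not tested.

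Over other splits of the samples, 48 h against control gave 559 calls and at most 37 in the other splits, and 96 h against control gave 2346 and at most 1; the 10 splits of each are too few for a share under 0.05. For 96 h against 48 h the real split gave 0 and another, with 96 h replicate 3 in place of 48 h replicate 3, gave 1081, which points to a structure of the samples that does not follow the labels. For both times against control, 3 of the 84 splits, the real one among them, gave at least the 1617 calls of the real split in a fit with 2 groups. That share lay under 0.05, the limit planned for chance. It does not show that infection is the source of the count, since other splits, which do not follow infection, gave more. Control replicate 1 and 48 h replicates 1 and 2 against the rest gave 1771. The highest of the others gave 2766, with 96 h replicates 1 and 2 and 48 h replicate 3 against the rest, again a structure of the samples.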

How the results depend on the processing

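Leaving out both replicate 3 arrays of the infected roots, the actin covariate and harvest day as a fixed block were chosen only after the results had been seen; the other alternatives were planned. No called gene or list changed direction under the settings recomputed here. Within harvest days the germin-like (1.73 and -0.10) and cell cycle (-0.17 and 0.03) differences of 96 h against 48 h changed sign, but each day held 1 array per time. The second values are from the day of 48 h replicate 3, which lay beside the 96 h arrays, so they say little. The 96 h calls, 1438 higher and 908 lower, were 2377 and 2401 without both replicate 3 arrays and 4919 and 5640 with arrayWeights. Counts for 48 h, 96 h, 96 h against 48 h and both times moved by over 1.5 times as follows, and the cause was not tested unless stated. Without a filter they were 186, 632 and, for both times, 720, with more probe sets tested; over log2 7 the 48 h count was 365. At an adjusted p under 0.01 they were 105, 327 and 434, and with a 2-fold minimum the count for both times was 1144. With only the groups compared the 48 h count was 205. With RNA yield as a covariate the 96 h count was 466 and that of both times 773. arrayWeights stopped before convergence and gave 5823, 10559, 10201 and 8667, which are not relied on. With replicate number as a block the counts were 217, 1022 and 1026; same-numbered arrays did not deviate together (r from -0.599 to 0.589 over 9 pairs), so the numbers do not pair the samples. Leaving out each array gave 122 to 724, 349 to 4472, 0 to 2122 (2122 without 48 h replicate 3) and 521 to 2373. Without both replicate 3 arrays of the infected roots the counts were 952, 4778, 2552 and 3352, and the actin covariate gave 46 for 96 h and 672 for both times. Leaving out each array gave a correlation of the responses between 0.537 (without 48 h replicate 3) and 0.928 (without 48 h replicate 2), against simulated means of 0.628 and 0.383 for unchanged groups of those sizes; the tolerance for this value, 1 SD of its leave-one-out values, was set after they were seen. With an estimated correlation 0 lists passed at each comparison; with fry 2 passed at 48 h and 0 for 96 h against 48 h. At 96 h, 8 lists passed, but 4 without a filter, 3 after quantile normalization, 4 with the replicate block and 4 with harvest day as a random block (consensus correlation -0.238). Leaving out each array gave 3 to 9 lists over the comparisons: 3 to 8 at 96 h, 9 without 96 h replicate 1 and 7 without 48 h replicate 3 for 96 h against 48 h, and 5 without control replicate 2 for both times. Of the 97 calls of named genes, 50 were lost with the replicate block, 8 after quantile normalization, 3 after median centring, 1 with trend and robust and 0 with harvest day. The last says little, since no control shared a harvest day with infected roots. Without control replicate 3, 63 were lost, 60 and 59 without 96 h replicates 1 and 2, 47 each without control replicates 1 and 2, 36, 19 and 7 without 48 h replicates 1, 2 and 3, and 14 without 96 h replicate 3. The measure of RNA quality, the 3 prime minus 5 prime difference at 96 h minus that in controls, was 0.361 over 5 probe set pairs, 0.808 and 0.748 for actin, 0.014 for cyclophilin, 0.100 for GAPDH and 0.136 for ubiquitin. Dim probe sets, near the floor of the values, limit the fold differences that can be seen.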

Other observations

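SWEET4, a sugar transporter gene, rose by 4.01 ± 0.93 at 96 h (log2 ± SE) and the sucrose synthase genes SUS6 and SUS5 by 3.21 ± 0.75 and 3.20 ± 0.83 (limma adjusted p = 0.0329, 0.0338 and 0.0439). Of 19 genes of sugar transport and sucrose cleavage 3 rose, and 5 adjusted over the list alone, though the list did not pass camera (adjusted p = 0.111). It passed fry (adjusted p = 0.0352), which does not compare it with other genes. ACO1, which makes ethylene from its precursor, rose by 3.51 ± 0.78 and EIL1B, a transcription factor gene of ethylene signalling, by 1.48 ± 0.39. They were 2 of 9 genes of the ethylene list, and 2 rose adjusted over the list alone; the list did not pass (camera adjusted p = 0.477). Of 7 germin-like genes GER6 and GER7 rose, the latter by 2.94 ± 0.68 (list camera adjusted p = 0.219). PRX112 rose 8.14-fold among 3 class III peroxidases, of which 2 had positive differences (list camera adjusted p = 0.486, fry adjusted p = 0.0101). LAC3 (3.22 ± 0.45), 4CLL1 (0.85 ± 0.16) and PAL06 (1.47 ± 0.30) were among 5 of 21 phenylpropanoid and lignin genes that rose, while 1 fell (list camera adjusted p = 0.195).

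Auxin, cytokinin and gibberellin genes went both ways at 96 h, while the called jasmonate (13 rose, 0 fell) and ethylene (2 rose, 0 fell) genes only rose. Called or not, 24 of 28 jasmonate genes had positive differences (median 0.85), but 4 of 9 ethylene genes did (median -0.06). Of 30 auxin genes 4 rose and 4 fell, and 5 rose and 11 fell adjusted over the list alone (camera adjusted p = 0.725). GH3-4, an enzyme gene that conjugates auxin, rose by 3.14 ± 0.45 and GH3-8 fell by 0.81 on the log2 scale. Among 18 cytokinin genes LOGL3 rose by 3.08 ± 0.73, and the response regulator genes RR1 and RR24 fell by 1.59 and 0.81 (0.829). CYP714C2 rose by 2.60 ± 0.59 (log2 ± SE) and D35 fell by 0.78 among 7 gibberellin genes (0.807). WRKY71 rose by 1.61 ± 0.31 among 6 WRKY genes (0.579), CRK6 by 2.48 ± 0.56 among 9 receptor-like kinases (0.475), HSP26.2 2.30-fold among 10 heat shock genes (0.577) and DHN1 by 0.81 ± 0.19 among 3 dehydrin and abscisic acid genes (0.892). LTP110-B, a lipid transfer protein gene, rose by 1.65 ± 0.17. Of the genes named here, SWEET4, SUS5, SUS6, ACO1, LOGL3, CYP714C2 and CRK6 had control means under log2 5 and RR1 a 96 h mean under log2 5, so the sizes of their differences are uncertain.

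Some large differences did not pass. The metallothionein genes MT2B, MT2C and MT2A had differences of 7.78 ± 2.22, 4.14 ± 1.21 and 3.04 ± 0.96 at 96 h (limma adjusted p = 0.0580, 0.0616 and 0.0745), and MT2B had control and 48 h SDs of 3.03 and 4.50. Over all probe sets 0 of the 7 metallothioneins passed limma, and 3 rose adjusted over the list alone. YSL13 and YSL15, of the iron acquisition list, had 3.11 ± 0.99 and -2.73 ± 1.23 (list camera adjusted p = 0.475), and PHT1;2, a phosphate transporter gene, had -2.39 ± 0.70 (phosphate list 0.931). The control means of MT2A and YSL13 lay under log2 5 (4.74 and 4.46), so the sizes of their differences are uncertain. Aquaporins (camera adjusted p = 0.899), glutathione S-transferases (0.475), hypoxia genes (0.807), mature-root transporters (0.899), histones (0.219) and the cellulose synthase family (0.990) did not pass as lists at 96 h. The camera direction of the auxin list was down with a median of 0.03 and a mean of -0.19, and the ethylene, dehydrin and phosphate lists had camera up with medians of -0.06, -0.08 and 0.25 and means of 0.54, -0.51 and -0.05. XTH8, a wall enzyme gene, had 0.04 ± 0.21.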
